A study of Drosophila melanogaster with 3 samples.

How the data were processed

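Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where a GFP-tagged clockwork orange protein (cwo) sat on the genome of Drosophila melanogaster embryos. Per the labels, whole embryos of mixed sex, aged 6 to 24 h by the source name, came from a transgenic line carrying cwo with GFP at its C-terminus, the precipitation used an antibody against GFP, and chromatin was sheared by sonication with a size range of 200 to 800. The 3 samples are biological replicates of 1 group by their labels, and no second condition was analysed here.

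The deposited files are lists of enriched regions, with a start, an end, a summit and a signal value per region, on the builds dm6 and dm3. Per the labels and the text deposited with each library, regions were called for each replicate against a single control alignment per build and again on the pooled reads of the replicates. Each of these relaxed lists holds exactly 30000 regions, because they include background for the irreproducible discovery rate (IDR) procedure. The optimal IDR list keeps regions that passed that procedure, and it equals the strongest regions of the pooled list by signal in both builds, 7366 of 7366 on dm6 and 8545 of 8545 on dm3. The peak caller, the aligner, their versions and the IDR threshold are not given in the sources used here. The signal column is the deposited score of the authors' peak caller, and its scale is not given in the sources used here. Median signal differed between the replicate lists, at 33.0, 44.2 and 65.2 for replicates 1, 2 and 3 on dm6, so signal was used only within a list, to rank regions. Read depth is unknown from these lists, so intervals below cover counting error over regions and not sequencing depth.

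Positions are 1-based on dm6, and no coordinate was moved between builds. Genes came from the Ensembl release 115 annotation of the same assembly, which holds 17683 genes and 35016 transcripts on arms 2L, 2R, 3L, 3R, 4 and X after transposable elements were left out. A replicate held an optimal region when the summit of that region lay inside 1 of its 7366 strongest regions. To leave out a replicate, the optimal list was cut to the regions that both others held. These were 6034, 5689 and 5706 regions without replicates 1, 2 and 3. The list still came from the pooled reads of all 3 replicates, so this is a stricter cut and not a new call. For replicate agreement itself, the mean over both others was used. Chance overlap came from 1000 shifts of the summits along their arms. Background regions were the 18722 pooled regions with a summit more than 1000 bp from every optimal summit, since these could have passed the IDR procedure. A summit within 1000 bp of a transcription start site (TSS) was counted at a promoter, and a gene was counted as bound when an optimal summit lay within 1000 bp of 1 of its TSSs. Motifs were searched within 100 bp of the summit on both strands. Shares carry 95% Wilson intervals. Shares were compared with two-sided Fisher exact tests, with Benjamini-Hochberg adjustment over all hexamer classes, over the 19 motifs or over the 16 gene lists. The trend of CACGTG with rank was tested with 100000 permutations across regions. Optimal counts per arm were compared with the background shares by a chi-square goodness-of-fit test. It takes those shares as fixed and leaves out their counting error. Regions are not independent replicates, so the same shares were also computed in each replicate and given as mean and SD.

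The definitions, the gene lists, the motifs and the rule for named genes were set before the data were examined. The rule names the 8 genes of the clock loop, the 20 protein-coding genes with the strongest promoter summit, the 3 bound members of each list with the highest signal, and the 5 strongest regions. Of the listed symbols, Aph-1, Ald and n-syb matched no single gene and were left out. The ribosomal protein list was drawn by symbol and takes in RpLP0-like, which is named for its similarity to a ribosomal protein and is not itself a cytosolic one. RpL24-like, RpL7-like and RpS28-like, with symbols of the same form, came in as well and were kept in every count. The alternatives tried were other distances, windows, overlaps and backgrounds, the strongest 3683 regions of the optimal list, the dm3 lists and the omission of each replicate, and those added after the data were seen were the strongest summit of each merged locus, promoter and other regions apart, the omission of secondary summits, the ribosomal protein list without RpLP0-like, the listed motifs with matched background and without secondary summits, and tests of X alone, which against arm length were exact binomial tests.

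The deposited lists contain pairs of close summits. On dm6, 849 neighbouring summits of the optimal list lay within 400 bp of each other, never closer than 199 bp and at a median of 205 bp, and in 820 of these pairs (96.6%) the summit at the higher coordinate was the weaker. The same held for 90.4% of 6606 pairs in the pooled list. Of the optimal summits, 810 (11.0%) had a stronger summit within 300 bp and are called secondary here. Those with the stronger summit at the lower coordinate, 795 in number, held CACGTG within 100 bp in 6.04% of cases and 180 to 300 bp toward the stronger summit in 16.7%. The main value of each comparison, the listed motifs, the gene lists and the number of regions at named genes were therefore also computed without secondary summits in either list, a choice made after the data were seen.

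Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The procedures were tested on simulated data with fixed seeds. The hexamer ranking placed a planted motif at rank 1 of all classes, and the overlap count recovered all 1377 shared regions of 2000. The gene list test called the planted list and 0 of the other lists among 101.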

Results

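Clockwork orange is a repressor of the bHLH-Orange family that acts in the circadian feedback loops of the fly, and the series maps the GFP-tagged protein in whole embryos aged 6 to 24 h. The data are 3 biological replicates of a single group, each a list of 30000 regions, with a pooled list and an optimal IDR list of 7366 regions on dm6. Overlapping intervals of the optimal list merge into 6543 loci. Signal is the deposited value of the authors' peak caller, and read depth is unknown. No group comparison is implied by the labels, so the regions that passed the IDR procedure were compared with those that did not, and the replicates with each other.

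The strongest regions were the same in the replicates. The first, at 2L:12002871-12004363, was intergenic with its summit 1137 bp from the nearest TSS, that of Hacd1, and ranked 1.33 ± 0.58 (SD, n = 3) in the replicate lists. The second, at 3L:18995545-18997709, lay in an intron of CG18135, and the third, at 2L:246601-247293, in an intron of kis, which encodes a chromatin remodeller. The fourth, at 2L:3354670-3355443, lay 176 bp upstream of E23, an ecdysone-induced ABC transporter gene. The fifth, at 2R:18805810-18807801, lay in an exon of lncRNA:CR44468. All 5 held CACGTG within 100 bp of the summit. Of the optimal regions, 88.1% ± 3.34 (SD, n = 3) were found in a replicate's strongest 7366, with 84.3%, 89.4% and 90.7% in replicates 1, 2 and 3. Regions found in all 3 numbered 5296 (71.9%), and 24 were found in none. Shifted summits gave 2.23% on average and at most 3.75% in a replicate. Across regions, signal of replicates 2 and 3 had a Spearman correlation of 0.837, against 0.790 for replicates 1 and 2 and 0.747 for replicates 1 and 3. The optimal list was derived from these same replicates, so its overlap with each is not independent evidence of agreement.

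Among the 8 genes of the clock loop, cwo, tim, Pdp1, vri, per and cry had an optimal summit at a promoter, and Clk and cyc had none. At cwo itself (FBgn0259938, 3R:10388258-10400752) the promoter summit at 3R:10388322 lay in the 5' UTR, 64 bp from a TSS, with a signal of 6356 and rank 24 of the optimal list; its replicate ranks averaged 23.3 ± 4.5 (SD, n = 3). The gene body and the 5000 bp upstream of it held 12 optimal summits. The strongest of these, at 3R:10394451 in an intron, ranked 15, and another at 3R:10384674, upstream of the gene, ranked 28. Both had CACGTG within 100 bp, and the promoter summit did not. The line is transgenic for cwo, and whether extra copies of this locus raised its signal was not analysed here. The summit of tim at 2L:3507407, in the 5' UTR, had a signal of 3852 and replicate ranks of 79 ± 5 (SD, n = 3), with CACGTG. Pdp1, an activator of the loop, had its strongest promoter summit at 3L:7867267 with rank 126, and 19 optimal summits in or upstream of the gene. The repressor vri had its strongest promoter summit at 2L:5305473 with rank 1523. At per, the summit at X:2685116 lay 464 bp from the TSS with CACGTG and ranked 2305. The photoreceptor gene cry had a weak region at 3R:19211679-19212158, rank 7090, which was in the strongest 7366 of 2 replicates. The region ranked 10077 in replicate 3. The cut to regions that both others held therefore dropped it without replicate 1 or 2, and 5 genes remained. The nearest optimal summit lay 6801 bp from a TSS of Clk and 2363 bp from a TSS of cyc. As a list, 6 of 7 clock loop genes that could have been bound were bound, with an adjusted p of 0.179 (Fisher exact test, two-sided).

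**Figure D1:**
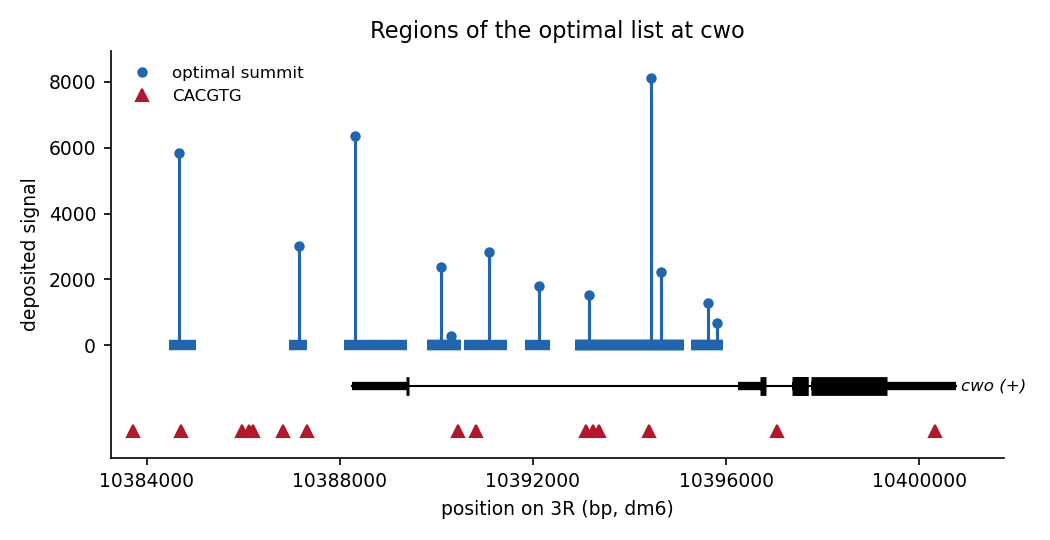
Optimal summits at cwo on 3R, dm6: each blue point is a summit at its position in bp (x axis) and its deposited signal (y axis), blue bars are the regions, black boxes are exons with coding parts thicker, and red triangles are CACGTG sequences. The view holds 12 summits and 15 CACGTG sites, and the strongest summit, with a signal of 8129, lies in an intron.

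The 20 protein-coding genes with the strongest promoter summits were led by CG18135, E23, CG11050, prage and Cftr, with ranks of 2, 4, 6, 7 and 12 in the optimal list. They were followed by CG30010, fok, Ugalt, CG16779 and MFS14, at ranks 17 to 23, and by cwo, Gpo1, srp, Hmgs and Orct2, at ranks 24 to 32. The last were Tina-1, CG7737, Acsf2, CG14100 and Prps, at ranks 35 to 42. Among them srp encodes a GATA factor of blood cells and fat body, Hmgs the hydroxymethylglutaryl-CoA synthase of the mevalonate pathway, Gpo1 a glycerol-3-phosphate oxidase and Ugalt a UDP-galactose transporter. All 20 regions were among the strongest 7366 of every replicate, and 13 held CACGTG. The signal of E23 was 16321 with replicate ranks of 4.33 ± 1.15 (SD, n = 3), and that of srp was 6002 with ranks of 27.3 ± 1.5 (SD, n = 3).

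Bound regions, the strongest of the pooled list, lay at promoters more often than the weaker background regions. Of the optimal summits 3966 (53.8%, 95% interval 52.7 to 55.0) were within 1000 bp of a TSS, against 6368 of 18722 background summits (34.0%, 33.3 to 34.7), an odds ratio of 2.26 (2.14 to 2.39; Fisher exact test, two-sided, p = 2.8e-188). The share was 54.3% ± 0.69 (SD, n = 3) in the strongest regions of the replicates and 34.9% ± 0.85 (SD, n = 3) in their other regions, so the gap exceeded the spread between replicates. Introns beyond promoter distance held 34.5% of the optimal and 43.2% of the background summits, 5' UTRs 10.4% and 7.50%, and coding exons 1.33% and 5.0%. The background leaves out pooled regions within 1000 bp of an optimal summit. Since 53.8% of optimal summits were at promoters, this can lower the promoter share of the background. Every alternative for promoter location kept this exclusion, so its effect was not tested.

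The E-box CACGTG, the site that bHLH-Orange and Myc-type proteins share, lay within 100 bp of 991 optimal summits (13.5%, 12.7 to 14.3) and of 1052 background summits (5.62%, 5.30 to 5.96), an odds ratio of 2.61 (2.38 to 2.86; Fisher exact test, two-sided, p = 5.2e-91). In the replicates the shares were 13.2% ± 0.18 (SD, n = 3) and 5.36% ± 0.31 (SD, n = 3). The share was higher than in the background in 3 of 3 replicates. Sites were concentrated at the summit. Their mean per 1000 regions and 20 bp bin was 21.6 within 40 bp of it and 2.61 between 300 and 500 bp away. Background regions had 7.21 and 2.25. Random positions away from optimal summits held CACGTG within 100 bp in 2.26% of cases, below the background share. Background regions may therefore include weaker cwo sites, and the comparison is of stronger with weaker regions. Among related sites, CACGCG, the class C site of Hes-type repressors, had an odds ratio of 1.5 (Fisher exact test, adjusted p = 1.2e-12), CACGTT 1.37 and CACGAG 1.25. The E-box variant CATATG passed narrowly, with an odds ratio of 1.14 (adjusted p = 0.047, Fisher exact test), but not without secondary summits (1.14, adjusted p = 0.056) or with background matched on GC content and promoter class (1.07, adjusted p = 0.51). CACAAG, CAGCTG, CAGGTG and CACATG did not pass the test, with odds ratios of 0.931, 1.02, 0.929 and 0.998; with the matched background CAGCTG passed, at 1.18 (adjusted p = 0.022, Fisher exact test). Of 7 control palindromes, 0 were more frequent in the optimal regions after adjustment and 1, TCCGGA, was less frequent, with odds ratios from 0.650 to 1.13 by Fisher exact tests. With the matched background the control GACGTC passed as well, at 1.31 (adjusted p = 0.038, Fisher exact test), against 3.10 for CACGTG. GAGAGA, the repeat of GAGA factor, had an odds ratio of 1.35, and TATCGATA, an element of housekeeping promoters, 1.81, which fell to 1.17 and did not pass with the matched background (adjusted p = 0.45, Fisher exact test).

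**Figure D2:**
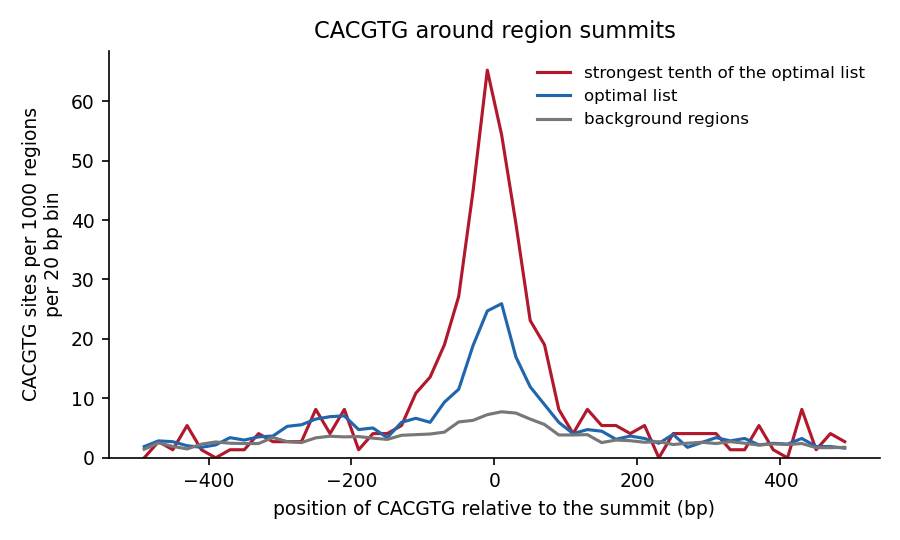
CACGTG sites per 1000 regions in 20 bp bins (y axis) by distance from the summit in bp (x axis), for the strongest of 10 bins of the optimal list (red), the optimal list (blue) and the background regions (grey). The red line averages 51.0 and the blue line 21.6 within 40 bp of the summit; the rise of the blue line at negative distances lies where secondary summits have their stronger neighbour.

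CACGTG ranked 1 among all hexamer classes by p and by odds ratio. Among the classes more frequent in the optimal regions, the next by p were ACGTGC, TTAAAA, ACACGT and TGATAA, the last in 20.8% of optimal and 14.9% of background regions (odds ratio 1.5, adjusted p = 1.0e-27, Fisher exact test, two-sided). TGATAA, CTTATC and CTGATA contain the core that GATA factors bind, and were singled out after their values were seen. In total 430 classes were more frequent and 634 less frequent in the optimal regions. Base composition differed between the sets, with a median GC content of 38.8% in the optimal and 41.8% in the background windows. With background matched on GC content and promoter class these counts fell to 124 and 132, A/T-only hexamers such as TTAAAA left the 30 leading classes, and CACGTG stayed first with an odds ratio of 3.10.

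Stronger regions held CACGTG more often. With the optimal list ordered by signal and parted into 10 bins, 217 of the 737 regions in the strongest bin held it (29.4%, 26.3 to 32.8), 18.2% in the next bin (15.6 to 21.1), and 7.61% in the weakest (5.91 to 9.75). Across regions the Spearman correlation of presence with strength was 0.161, with a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. The strongest bin of the replicate lists held CACGTG in 28.9% ± 0.87 (SD, n = 3) and the weakest bin in 7.20% ± 1.83 (SD, n = 3).

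**Figure D3:**
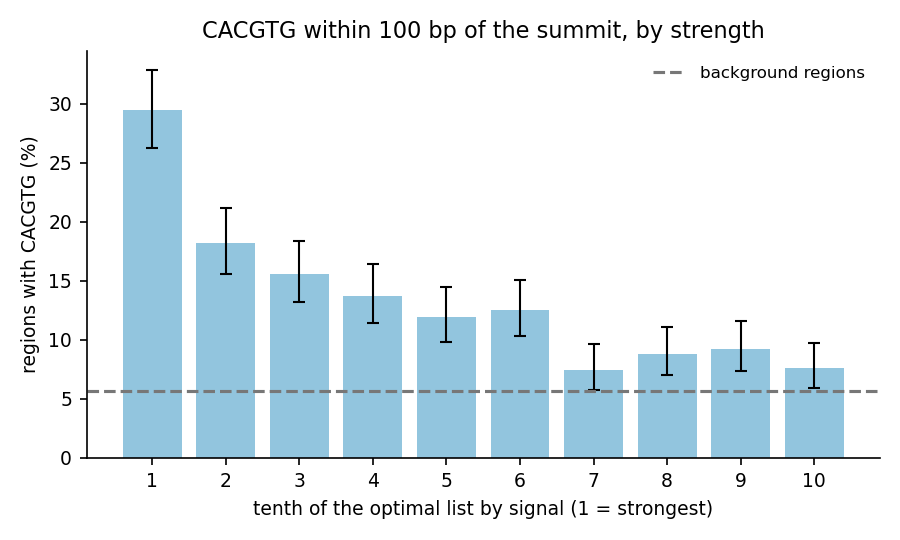
Share of regions with CACGTG within 100 bp of the summit (y axis, percent) in each of 10 bins of the optimal list by signal (x axis, 1 is the strongest), with 95% Wilson intervals; the dashed line is the background share. The share is 29.4% in the strongest and 7.61% in the weakest bin, against 5.62% in the background.

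Genes of ribosome production and of the Myc and Max list were bound more often than other genes. Optimal summits lay at the promoters of 3535 of the 7149 protein-coding genes that had a pooled summit there (49.4%). Of ribosomal protein genes 64 of 79 were bound (81.0%; Fisher exact test, two-sided, adjusted over the 16 lists, p = 1.5e-07), with RpL7 and RpS27 among the strongest at ranks 498 and 694. The strongest region of the list, at rank 300, was that of RpLP0-like, which the symbol brought in and which is not itself a cytosolic ribosomal protein, and without it 63 of 78 were bound. RpL24-like and RpL7-like, both bound, and RpS28-like, not bound, also came in by symbol and stayed in both counts. Of nucleolar genes 17 of 18 were bound (adjusted p = 0.00051, Fisher exact test), led by Nnp-1, Surf6 and Fib, and the unbound member was Dbp73D. The nucleolar list was labelled as of Myc type when it was drawn up. The Myc and Max list holds bHLH factors as well as bHLH-leucine zipper factors. All 8 of its tested genes were bound (adjusted p = 0.019, Fisher exact test). SREBP, Mondo and Mnt had the highest signal, and Myc, Max, bigmax, crp and tx made up the rest. No count leaves out single members such as tx. The call for this list ended in the strongest 3683 optimal regions, with 62.5% bound against 30.4% of other genes and an adjusted p of 0.164 (Fisher exact test). Over all alternatives its adjusted p ranged from 0.00245 to 0.164.

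Hox and patterning genes were bound less often: 0 of the 8 tested, Abd-B, Antp, abd-A, bcd, cad, hh, odd and wg, had an optimal summit at a promoter (upper 95% bound 32.4%; adjusted p = 0.031, Fisher exact test, two-sided). All 8 had a pooled summit at a promoter, as every tested gene did, so unbound here means without an optimal summit. With the cut that leaves out replicate 1, 2 or 3 the call for this list was lost (adjusted p of 0.051, 0.098 and 0.078, Fisher exact tests). It was lost as well in the strongest 3683 optimal regions (adjusted p = 0.265, Fisher exact test). In these cuts still 0 of the 8 were bound, but the share of other genes was lower, at 42.7%, 41.4%, 41.6% and 30.5%. The call was also lost with the nearest gene within 5000 bp, where 38.5% were bound. Over all alternatives its adjusted p ranged from 0.00246 to 0.748 (Fisher exact tests). The other lists did not pass after adjustment. With all protein-coding genes as background, the clock loop, Notch pathway and glycolysis lists passed as well (adjusted p of 0.011, 0.0082 and 0.011, Fisher exact tests). There 10 of 33 V-ATPase subunits, 4 of 24 members of the tissue bHLH list and 5 of 23 neuronal genes were bound. The share of all protein-coding genes was 25.3%, and glycolysis stayed at 9 of 15. The counts that follow leave out listed genes with no pooled summit at a promoter. Of the Notch pathway 11 of 14 genes were bound (adjusted p = 0.106, Fisher exact test), with gro, the corepressor of bHLH-Orange proteins, kuz and numb the strongest. Of the bHLH-Orange genes 5 of 7 were bound, cwo, hry, E(spl)m3-HLH, E(spl)m7-HLH and E(spl)mbeta-HLH. The clock kinase list also holds phosphatase subunits and F-box proteins that act on clock proteins. Of its 10 tested genes 5 were bound, led by nmo, sgg and wdb. The tissue bHLH list holds tissue-specific bHLH activators and their partners. Of its 8 tested genes 4 were bound, led by trh, net and emc. V-ATPase subunits were bound in 10 of 17 tested cases, with Vha44, Vha16-1 and Vha55 the strongest and all with CACGTG. The Vha44 summit is that of Hmgs. In the list of glycolysis and lactate metabolism 9 of 15 genes were bound, led by Gapdh2, Hex-A and Treh. Among tissue lists, bound genes numbered 5 of 14 for neurons (elav, Syx1A, fne), 3 of 6 for glia (moody, loco, Gli), 7 of 18 for muscle (Msp300, Mef2, Tm1), 8 of 15 for epidermis and trachea (trh, which is also in the tissue bHLH list, cora, crb) and 6 of 10 for fat body and hemocytes (srp, fkh, ush), naming the strongest of each. The tissue names are labels of the lists as drawn up, and members such as fkh need not be specific to the named tissue.

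**Figure D4:**
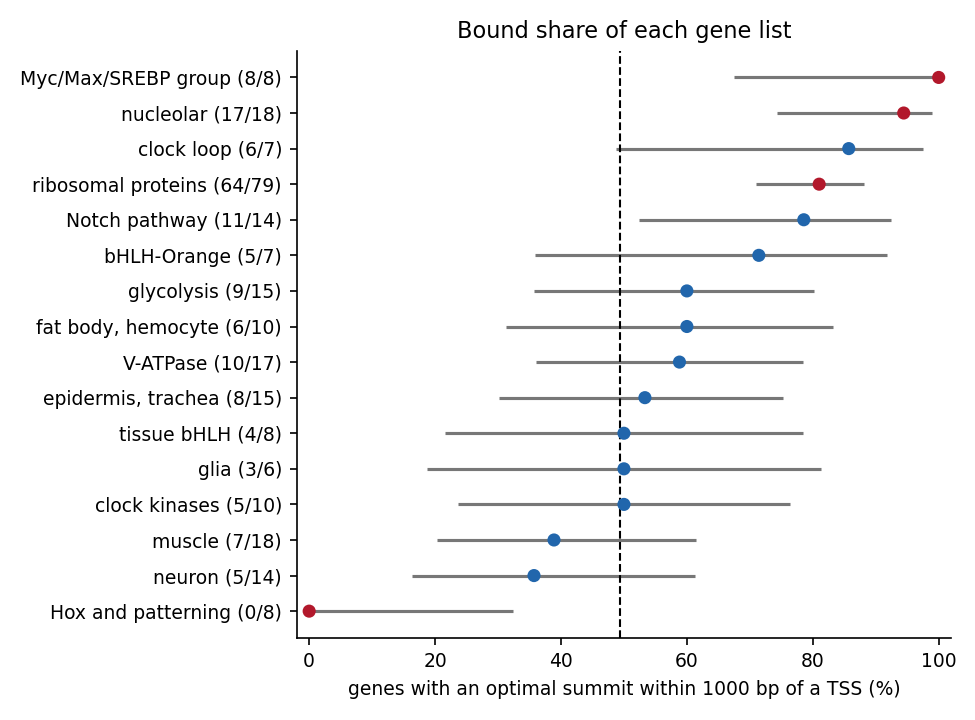
Percent of tested genes in each list with an optimal summit within 1000 bp of a TSS (x axis), with 95% Wilson intervals as grey lines and bound over tested genes beside each list name; red points passed the Fisher exact test after adjustment, blue points did not, and the dashed line is the share of all tested genes. Ribosomal protein genes stand at 81.0% and Hox and patterning genes at 0%, against 49.4% of all tested genes. The list named clock kinases also holds phosphatase subunits and F-box proteins, and the list named tissue bHLH also holds partners of bHLH activators.

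The X chromosome held a smaller share of bound regions than of background regions. It carried 1208 optimal regions (16.4%, 15.6 to 17.3) and 18.6% of background regions, an odds ratio of 0.860 (Fisher exact test, two-sided, p = 3.8e-05). Over the 6 arms the optimal counts differed from the background shares, taken as fixed (chi-square goodness-of-fit test, p = 1.3e-06). In the replicates the X share was 16.4% ± 0.06 (SD, n = 3) among the strongest regions and 17.9% ± 0.81 (SD, n = 3) among the others, and it was lower in all 3. The gap was smallest in replicate 1, at 16.4% against 17.1%, and largest in replicate 3, at 16.3% against 18.7%. Arms 2L, 2R, 3L and 3R carried 55.6 to 58.2 optimal regions per Mb and X 51.3. In the full pooled list X held 17.7% of regions, near its 17.6% of arm length. The optimal list is a cut of that list by signal, and the embryos were of mixed sex. Whether the X copy number lowered signal there was not analysed here. Chromosome 4 carried 6 optimal and 15 pooled regions, where its length alone would give 302 of the pooled list; this arm was singled out after its values were seen, and whether filtering or mappability lowered its count was not analysed here.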

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

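The omission of secondary summits, the use of the strongest summit of each merged locus, the separation of promoter from other regions, the tests of X alone, the ribosomal protein list without RpLP0-like and the alternatives for motifs other than CACGTG were chosen after the data were seen. Promoter location, CACGTG at summits, its leading place among hexamers, its trend with rank and the lower X share kept their direction and their side of the threshold under every alternative run. Their odds ratios ranged from 2.22 to 4.39 for promoters and from 2.23 to 7.12 for CACGTG. Leaving out secondary summits gave 2.30 and 2.64. The X share differed from its comparison by -1.18 to -2.47 percentage points, with p of at most 0.0074 (exact tests, two-sided). Replicate agreement moved with how it was counted: 79.2% with a reciprocal overlap of at least 50%, 51.6% with the strongest 3683 regions of each replicate, which by construction cannot hold the whole list, 98.9% with all their regions and 98.6% for the strongest 3683 optimal regions. The number of gene lists past the threshold was 4. It was 7 with all protein-coding genes as background. That adds the clock loop, Notch and glycolysis lists and tests genes with no pooled region at a promoter. The number was 2 for the strongest 3683 optimal regions. There the Hox list had the fewest bound genes possible, 0 of 8, and still p = 0.116 before adjustment (Fisher exact test). It could not have passed as less bound there. The Myc and Max list had 5 of 8 bound and an odds ratio of 3.81, and the cause of its lost call was not tested. Leaving out each replicate gave 86.9% to 90.0% for agreement. The optimal regions that both others held gave 3 gene lists each time and 5 to 6 clock genes. This cut does not remove the reads of the replicate left out from the pooled list. Among the values for single lists, genes and motifs, 311 were counted as unchanged. For a list or motif this meant that direction and side of the threshold were kept, with ACCGGT, at 0.928, coming to 1 with matched background. For a gene it meant only that at least 1 promoter region was left, and the genes had been named because they were bound. A further 11 lost their call, for the Hox list, the Myc and Max list, cry, CATATG and TATCGATA, and 2 gained one, for CAGCTG and GACGTC. Odds ratios below 1 that had not passed turned above 1, also without passing, with matched background for CACAAG (1.01), CAGGTG (1.02), CACATG (1.12) and TGCGCA (1.04), and without secondary summits for TGCGCA (1.01), where the cause was not tested. Read depth is unknown, so what it limits could not be measured.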

Other observations

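The tests of this part were set out before their own results were seen, after the patterns they address had been noticed, and the test of coding exons was added once the flank shares had been seen. The values without secondary summits, the test of TGATAA in regions without CACGTG and the flank shares and test at pooled summits were chosen after the data were seen. Optimal loci were also grouped where neighbouring summits lay within 10000 bp. The group with the most loci, 26, lay at 3R:16202799-16256612 over tara and its neighbours, with CACGTG at the summit of 2. The next, with 21 loci, lay at 3L:8672431-8709284 and covers hry, a pair-rule repressor of the same protein family as cwo, with CACGTG at the summit of 4. A group of 19 loci lay at 2L:1611082-1657267 over chinmo and its neighbours, and a group of 15 at 3L:7850773-7882344 over Pdp1 and CG32365. These groups were chosen after their values were seen.

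Binding at ribosomal protein and nucleolar gene promoters was weighed against the E-box and the number of TSSs. At nucleolar genes 52.2% of 23 optimal promoter regions held CACGTG, against 12.8% of the other optimal promoter regions (Fisher exact test, two-sided, p = 7.1e-06). Without secondary summits the share at nucleolar genes was 61.1%. This list was labelled as of Myc type when it was drawn up, and Myc-type proteins share this site. Its E-box share may reflect that choice, so the E-box is only a candidate explanation there. At ribosomal protein genes the share was 20% of 80 regions against 12.8% (Fisher exact test, two-sided, p = 0.065), which does not decide whether the E-box plays a part. Random lists matched on the number of TSSs held fewer bound genes than the ribosomal protein list, with a permutation p of 0.00020 (two-sided), the smallest that 10000 lists can give, which argues against TSS number as the whole cause. Signal at active promoters that does not depend on cwo stays open, since no track of the control was analysed here, and no biological explanation was tested.

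The GATA-type hexamer TGATAA was weighed against base composition and against the E-box. With background matched on GC content and promoter class its odds ratio was 1.41 (1.29 to 1.53), above the 95th percentile of 1.15 among 59 other hexamers of the same bases, which argues against base composition as the whole cause; without secondary summits it was 1.43. TGATAA was in 20.4% of optimal regions with CACGTG and in 20.9% of those without (odds ratio 0.969, 0.821 to 1.14; Fisher exact test, two-sided, p = 0.74). Among regions without CACGTG it was in 20.9% of optimal and 15.9% of matched background regions (odds ratio 1.40, 1.28 to 1.53; Fisher exact test, two-sided, p = 1.5e-13), which argues against the E-box as the whole cause. No biological explanation was tested.

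Of 16428 CACGTG sites on the arms 1033 (6.29%) lay within 100 bp of an optimal summit. The share was 10.8% (8.63 to 13.4) for TCACGTGA and 0.49% (0.21 to 1.14) for CCACGTGG, and a chi-square test over the 10 flank classes gave p = 4.9e-69, which argues against equal binding of all flanks. Much of this gap lay in whether a site was at any pooled summit, as 21.7% and 2.94% were; among those sites 49.7% of 143 (41.6 to 57.7) and 16.7% of 30 (7.34 to 33.6) were bound, with p = 8.2e-09 over the 10 classes (chi-square test). Coding exons held 17.6% of TCACGTGA and 46.3% of CCACGTGG sites. Outside coding exons the shares were 12.9% (10.3 to 16.0) and 0.73% (0.28 to 1.86), so location in coding exons is unlikely to be the whole cause, and a preference of cwo or of a partner for some flanks stays a hypothesis, with no biological explanation tested.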
